A study of Homo sapiens with 4 samples.

How the data were processed

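RNA sequencing was carried out on U2OS cells, an established human osteosarcoma line, in 4 libraries: 2 from wild type cells and 1 from each of 2 clones recorded as HMCES knockouts. Per the labels, cultures were collected while growing, total RNA was purified on columns, libraries came from an Illumina TruSeq total RNA kit, and paired reads of 75 bases were read on an Illumina HiSeq instrument. The labels put the knockout cells at passage 41 and give no passage for the wild type cells. They do not say how the clones were made, or whether the wild type libraries came from separate cultures.

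Per the submitters' processing notes, the tools were FastQC, HISAT2, featureCounts, edgeR and Cufflinks, with hg38 as the genome build. Versions other than that of featureCounts are not given in the sources used here. The count of read pairs per gene was made with featureCounts 1.5.0-p3, per the file headers, with a mapping quality minimum of 30, both mates required to map, and pairs split between chromosomes left out. No strand option appears in the command, so reads of a gene and of an antisense partner are counted together. No option for multiple mapping or overlapping genes appears either, so reads with equal matches to several gene copies, or to overlapping genes, were left out of the counts, and genes with near-identical copies are undercounted. The authors deposited these counts without normalization for 26485 genes. They also deposited TPM values per gene symbol, in which a row without a gene name holds 73.8% of the TPM of wild type 1, 19.2% of wild type 2, 68.1% of clone 1 and 88.6% of clone 2. That row was left out of every test on TPM. The row of MIR1244-1 holds 47.0% of the TPM of wild type 2 and 0 in wild type 1 and in both clones. A further file, the authors' deposited table of their edgeR comparison, holds a log2 fold change, a mean log2 CPM, a p-value and an adjusted p-value (FDR) for 13397 genes. In that table no gene was below 1.00 CPM in any library, and every gene outside it fell to 0.993 CPM or less in some library, so the table holds the genes with at least 1 CPM in every library. 0 columns of per-sample values were left unused.

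The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with trimmed mean of M values (TMM) scaling, filterByExpr, robust estimation and Benjamini-Hochberg adjustment at 0.05, over all 4 libraries and without a block. It tested 16596 genes, with a common biological coefficient of variation of 0.192. Fold changes are log2, knockout over wild type, with a standard error (SE) taken from the test statistic. Normalised values are TMM-scaled CPM, that is, counts scaled to a common library total. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry. With an estimated correlation, camera rests on the few residual degrees of freedom that 4 libraries leave, so a list passes less easily at any correlation. The list of E2F and replication genes had an estimated correlation of -0.014, below the preset, yet its unadjusted camera p went from 0.000993 to 0.0608. Of 948 list members, 933 were matched to the count table, through older symbols where needed, and 816 passed the filter. The 34 lists cover DNA repair and replication, p53 targets, stress and signalling responses, metabolism, lineage markers and neighbours of HMCES. The list of mitochondrially encoded genes has 13 members, of which 0 matched, so 33 lists were tested. Chromosomes were tested the same way, with the genes that the file places on 1 primary chromosome.

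The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named HMCES, up to 12 protein-coding genes that rose and 12 that fell at an adjusted p under 0.05 with a mean CPM of at least 1 and no overlap between the groups, and of each list up to 4 members with the smallest p. It gave 129 genes, of which the text describes a part. Genes from the authors' deposited table are given as that table's items, and any other gene is said to have been chosen after its values were seen.

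The alternatives tried were DESeq2 size factors, library totals, no filter on low counts, a filter of 1 CPM in at least 2 libraries, the DESeq2 Wald test (DESeq2 1.42.0), edgeR's exact test, limma on log2(TPM + 1), the replicate number as a block, and each library left out in turn. With a library left out, its group holds 1 library, which is assumed to vary like the other group. Added after the data were seen were edgeR's likelihood ratio test with and without the authors' filter, that filter in the main test, TPM rescaled to a common median ratio, wild type 2 thinned to the depth of wild type 1, each clone set against a different wild type library, and a fit with each library's trend of log2 CPM with exon length removed by lowess.

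The tests were tried on simulated data for this comparison, with 200 changed genes per simulation among 16371 genes. The quasi-likelihood test called 7.2% of genes changed 2-fold, 70.4% of those changed 4-fold, 92.8% of those changed 8-fold and 96.8% of those changed 16-fold, with at most 11 false calls in a simulation. The exact test called 46.0% of genes changed 2-fold, with up to 82 false calls. A list shifted by 0.4 on the log2 scale was called in 10 of 10 simulations. Genes were drawn independently there, so the simulations do not test the preset correlation. In the real lists the estimated correlation ran from -0.096 for haematopoietic markers to 0.65 for replication-dependent histones, with p53 targets at 0.056. Among the called lists it ran from -0.033 for mismatch repair to 0.45 for ribosomal proteins, with YAP and TAZ targets at 0.31. Where the true correlation exceeds the preset 0.01, camera at the preset gives too small a p-value. A length trend of -0.3 log2 per doubling of exon length, put into 1 library, moved the ribosomal protein list by -0.30 on the log2 scale. Removing the trend brought it to 0.0037. That slope was set rather than fitted to wild type 2, so the simulated shift does not measure the effect of the real trend. With the real trend removed, the median of the list was -0.17. Total counts per library were 54913193 and 110811565 for the wild type libraries and 48989090 and 48779516 for the clones, and 3 counts in a library correspond to 0.0271 to 0.0615 CPM. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.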

Results

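Gene expression was measured by RNA sequencing in wild type U2OS osteosarcoma cells and in U2OS clones recorded as knocked out for HMCES, a protein that binds covalently to abasic sites in single-stranded DNA and shields them during replication. There were 2 wild type libraries and 2 HMCES knockout clones with 1 library each, and both clones were at passage 41. Wild type 2 held 110811565 counts, and the other 3 libraries held 48779516 to 54913193. Nothing in the labels says that the wild type libraries came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera at its preset correlation takes its error mainly from the spread among genes, so its small p-values do not measure variation between cultures. With an estimated correlation or with fry, 0 of 33 lists passed.

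Wild type 2 stood apart from the other 3 libraries in more than depth. The median absolute difference between libraries was 0.27 log2 CPM for the wild type pair and 0.16 for the clones, and wild type 1 differed by 0.17 from clone 1 and by 0.15 from clone 2. Against wild type 1, genes with under 1000 bases of exon were higher in wild type 2 by a median of 0.25 log2 CPM, and genes of 8000 bases or more were at -0.24. The clones showed no such trend with length. Ribosomal protein genes took 5.46% of counts in wild type 2 against 3.95% to 4.16% in the other 3 libraries. For the called gene lists, results that move with this library are given with its values. Many single genes are given only as a log2 fold change and SE, and some of these also rest largely on wild type 2. RMI2, for example, stood at 15.2 CPM in wild type 1 and 25.9 CPM in wild type 2, against 13.6 and 9.67 CPM in the clones.

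**Figure D1:**
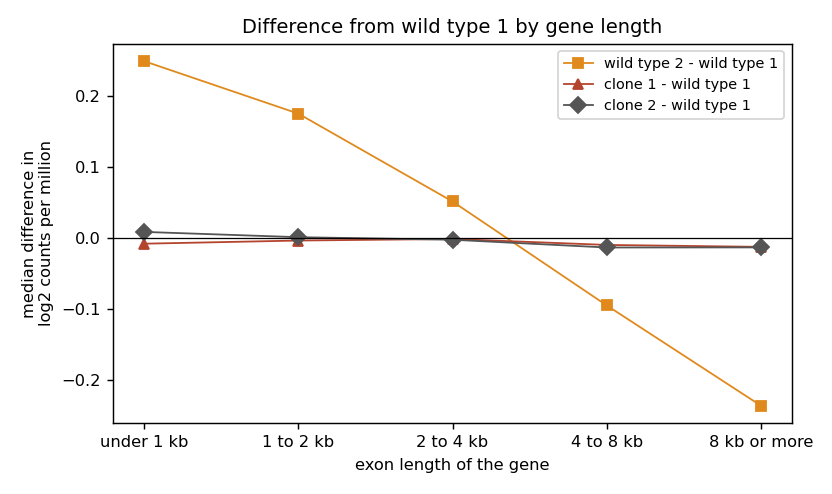
Median difference in log2 CPM from wild type 1 (vertical axis) over genes grouped by exon length (horizontal axis), for wild type 2 and each clone. Wild type 2 goes from 0.25 for genes under 1000 bases to -0.24 for genes of 8000 bases or more, and both clones stay between -0.01 and 0.01.

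HMCES mRNA was lower in both clones than in both wild type libraries, and it was still present. The gene, on chromosome 3 (129278841 to 129305292, hg38), stood at 59.0 and 76.6 CPM in wild type 1 and 2, at 41.9 CPM in clone 1 and at 23.1 CPM in clone 2. The log2 fold change was -1.06 ± 0.29 (SE, n = 2 and 2), with an adjusted p = 0.765 in edgeR's quasi-likelihood test. Fitted clone by clone, it was -0.69 in clone 1 and -1.55 in clone 2. In the authors' deposited table the log2 fold change of HMCES is -1.06 with an adjusted p = 0.151. With clone 1 left out the difference passed the test, at -1.55 with an adjusted p = 0.0248.

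The series asks which genes change in the knockout clones, and neither protein nor the edited sequence was examined here. The clearest change was the near loss of NLRP2, a member of the NOD-like receptor family, on chromosome 19 (54965284 to 55001142). It stood at 11.5 CPM in each wild type library, 0.406 CPM in clone 1 and 0.265 CPM in clone 2, a fall of 34.0-fold (log2 fold change -5.09 ± 0.31 SE, n = 2 and 2, adjusted p = 0.0179). It was the only gene of 16596 past the threshold in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 889 genes, 516 higher and 373 lower, against 830 from evenly spread p-values and 355 and 438 when wild type 1 was grouped with clone 1 or clone 2. The DESeq2 Wald test called 49 genes (31 up, 18 down) and edgeR's exact test 44 (23 up, 21 down), the latter against 0 and 9 in those 2 other groupings. Those groupings put a clone and a wild type library in each group, so any difference between clones and wild type adds to the spread within groups. That lowers their counts, which therefore do not measure what chance alone would give. In 38.9% of genes the clones did not overlap the wild type libraries, against 33.3% by chance. Without wild type 2 the test called 0 genes, and the gene NLRP2 had about the same fold change with an adjusted p = 0.869. Without wild type 1, clone 1 or clone 2 it called 236, 38 and 22.

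**Figure D2:**
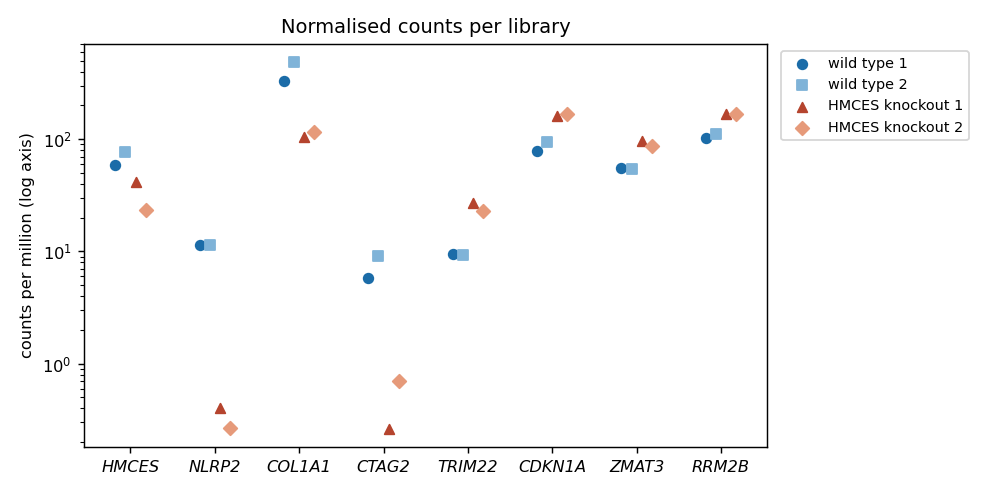
CPM on a log axis (vertical) of 8 genes (horizontal) in each of the 4 libraries, 1 point per library. HMCES, NLRP2, COL1A1 and CTAG2 were lower in both clones than in both wild type libraries, and TRIM22, CDKN1A, ZMAT3 and RRM2B were higher.

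The authors' deposited table, an edgeR comparison of the same libraries, calls 22 genes at an adjusted p under 0.05, of which 17 rose and 5 fell. COL1A1, the main chain of type I collagen, leads it with a log2 fold change of -1.89 in the authors' deposited table and its adjusted p = 9.87e-11. Genes that rose in the authors' deposited table include the interferon-inducible TRIM22 (1.42), the giant membrane protein gene CSMD3 (1.81), the hemidesmosome collagen COL17A1 (1.36), the SNARE gene VAMP8 (1.60) and the epithelial adhesion gene EPCAM (1.41), all log2. Genes that fell there include ZNF283 (-1.15) and the intermediate filament gene NES (-1.09). U2AF1, a splicing factor gene, is listed there at -2.59. Its exons are placed at 2 sites far apart on chromosome 21, so reads shared between copies make its value uncertain. In the main fit here each of these 22 genes had an unadjusted p under 0.05 and 0 passed after adjustment, COL1A1 with an adjusted p = 0.214. Fold changes in both tables correlated across 13397 genes at r = 0.99999 (genes are not independent replicates). The filter behind the authors' deposited table leaves out 3199 genes tested here, NLRP2 among them. Its 22 calls were all recovered with edgeR's likelihood ratio test and that filter.

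As a list, targets of the tumour suppressor p53 were higher in both clones, by camera at its preset correlation (adjusted p = 9.14e-10). The list did not pass with an estimated correlation (adjusted p = 0.576 with an estimated correlation) or with fry (adjusted p = 0.271). As 4 libraries leave the test with an estimated correlation few degrees of freedom, not passing there does not show that correlation accounts for the call. Of 29 measured members, 28 had a positive log2 fold change, with a median of 0.32, and 20 were higher in both clones than in both wild type libraries. CDKN1A, the inhibitor of cyclin-dependent kinases p21, had a log2 fold change of 0.92 ± 0.15 (SE, n = 2 and 2) and stood at 77.9 and 94.7 CPM in the wild type libraries against 160 and 167 in the clones. The RNA-binding protein gene ZMAT3 was at 0.75 ± 0.13, the ribonucleotide reductase subunit gene RRM2B at 0.66 ± 0.13 and the antiproliferative gene BTG2 at 0.69 ± 0.15. These 4 and 6 others passed the test when adjusted over the list alone, and 0 passed over all genes in the main test. The authors' deposited edgeR comparison calls CDKN1A (adjusted p = 0.000933), ZMAT3 (0.00785) and RRM2B (0.0490) over all its genes, but not BTG2 (0.0994). The 6 others were DDB2 (0.63), which recognises damaged DNA, EDA2R (0.64), TP53INP1 (0.71), MDM2 (0.48), the ubiquitin ligase that degrades p53, FAS (0.60), a death receptor, and PLK3 (0.54), of which all but DDB2 were chosen after their values were seen. The camera call held without any 1 library, with medians from 0.32 to 0.48, the highest without wild type 2, and it was higher in wild type 2 than in wild type 1 by 0.11.

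**Figure D3:**
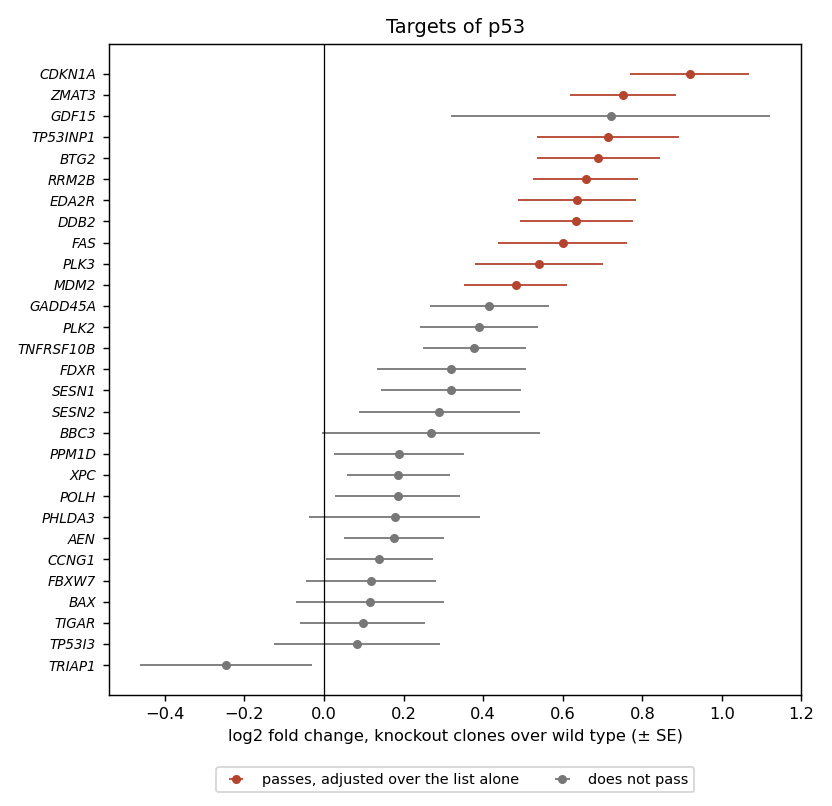
Log2 fold change of the knockout clones over wild type (horizontal axis, ± SE, n = 2 and 2) for the 29 measured targets of p53 (vertical axis). The 10 genes that pass when adjusted over the list alone are in red, the highest CDKN1A at 0.92, and 1 gene of the list lies below 0.

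Another 6 lists were higher by camera at its preset correlation. Inflammatory and secretory genes had a median log2 fold change of 0.33 (adjusted p = 0.000839, and adjusted p = 0.576 with an estimated correlation), with RELB, a subunit of NF-kappaB, at 0.70 ± 0.21 (SE), its inhibitor NFKBIA at 0.68 ± 0.27, and the cytokine gene CSF2 at 1.87 ± 0.63 from a level under 1 CPM. Immediate early genes had a median of 0.23 (adjusted p = 0.0154, and adjusted p = 0.581 with an estimated correlation), with DUSP1 at 0.56 ± 0.16 and NR4A1 at 0.70 ± 0.25. Targets of the growth regulators YAP and TAZ had a median of 0.24 (adjusted p = 0.0176, and adjusted p = 0.614 with an estimated correlation), with AMOTL2 at 0.53 ± 0.20 and RBMS3 at 0.48 ± 0.16. Cytidine and adenosine deaminases had a median of 0.29 (adjusted p = 0.0296, and adjusted p = 0.576 with an estimated correlation), with APOBEC3C at 0.50 ± 0.15. HOX genes had a median of 0.26 (adjusted p = 0.0383, and adjusted p = 0.623 with an estimated correlation), with HOXB9 at 0.38 ± 0.18. Interferon-stimulated genes had a median of 0.19 (adjusted p = 0.0389, and adjusted p = 0.614 with an estimated correlation), in which TRIM22 was at 1.41 ± 0.18 and IFIT1 at -0.86 ± 0.30. Of all these members, 0 passed over all genes in the main test, and TRIM22 alone passed when adjusted over its list alone. The same lists were lower in wild type 2 than in wild type 1, with medians from -0.36 for immediate early genes to -0.17 for HOX genes. Without wild type 2 each lost its call, with adjusted p = 0.170 (median 0.24) for inflammatory genes, 0.333 for immediate early genes (0.11) and for YAP and TAZ targets (0.08), 0.272 for deaminases (0.21) and HOX genes (0.09), and 0.389 for interferon-stimulated genes (0.10). Without wild type 1 the medians of the inflammatory, immediate early, YAP and TAZ, and interferon lists were 0.58, 0.51, 0.44 and 0.36, and the deaminase and interferon calls ended (adjusted p = 0.0550 and 0.0533). Without clone 1 the immediate early and interferon calls ended (adjusted p = 0.0715 and 0.413, medians 0.24 and 0.08). Without clone 2 the immediate early, YAP and TAZ, deaminase and HOX calls ended (adjusted p = 0.0681, 0.295, 0.823 and 0.982, medians 0.26, 0.12, 0.23 and 0.06, the HOX test turning to the other direction), and the inflammatory median was 0.52.

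**Figure D4:**
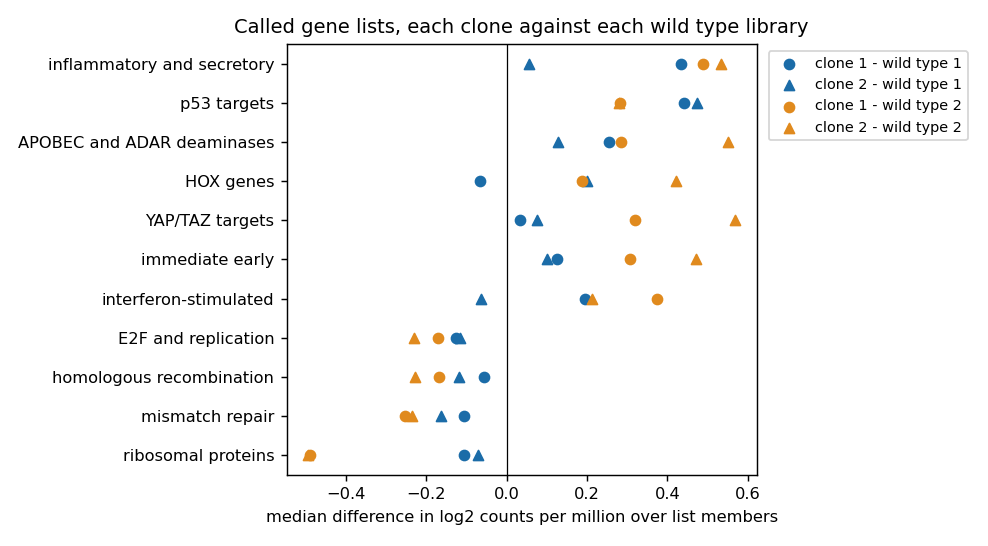
Median difference in log2 CPM over the members of each of the 11 called lists (vertical axis), for each clone against each wild type library (horizontal axis). For ribosomal protein genes the medians were -0.49 against wild type 2, but -0.11 and -0.07 against wild type 1.

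Ribosomal protein genes and 3 lists of DNA replication and repair genes were lower by camera at its preset correlation, and by fry the lowest adjusted p was 0.166. Ribosomal protein genes had a median log2 fold change of -0.30 over 72 members (adjusted p = 8.56e-09, and adjusted p = 0.605 with an estimated correlation), and 44 were lower in both clones than in both wild type libraries. RPS18 was at -0.83 ± 0.30 (SE), RPL24 at -0.73 ± 0.26 and RPS21 at -0.88 ± 0.35. They were also higher in wild type 2 than in wild type 1 by a median of 0.42, and their median was -0.09 without wild type 2 and -0.49 without wild type 1. Targets of E2F and replication genes had a median of -0.14 over 39 members (adjusted p = 0.00819, and adjusted p = 0.576 with an estimated correlation), with the replicative helicase subunit gene MCM6 at -0.47 ± 0.15. Mismatch repair genes had a median of -0.21 (adjusted p = 0.0115, and adjusted p = 0.576 with an estimated correlation), with the sliding clamp gene PCNA at -0.35 ± 0.17 and RFC4 at -0.31 ± 0.15. Homologous recombination genes had a median of -0.15 (adjusted p = 0.0240, and adjusted p = 0.576 with an estimated correlation), with RMI2 at -0.82 ± 0.30. No member passed over all genes or when adjusted over its list alone. Between wild type 2 and wild type 1 the medians of these 3 differed by 0.02, 0.13 and 0.09. Without wild type 2 the 3 lists kept their calls, at medians of -0.11, -0.13 and -0.10, and without wild type 1 homologous recombination lost it (adjusted p = 0.0550). They lost their calls without clone 1 (adjusted p = 0.0715, 0.0918 and 0.0918, medians -0.19, -0.16 and -0.19) and without clone 2 (0.196, 0.148 and 0.231, medians -0.13, -0.20 and -0.11), so the medians stayed negative.

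The remaining 22 lists did not pass in the main test. Among them, base excision repair, the pathway that removes abasic sites, had a median log2 fold change of -0.05 over 25 genes (adjusted p = 0.426), with the uracil glycosylase gene UNG at -0.34 ± 0.13 (SE) and XRCC1 at 0.34 ± 0.15. Translesion synthesis and damage tolerance genes had a median of -0.10 (adjusted p = 0.114), the Fanconi anaemia pathway -0.13 (0.0516), the replication checkpoint -0.16 (0.0600), nucleotide excision repair -0.01 (0.925) and end joining -0.05 (0.448). With the length trend removed, translesion, Fanconi, checkpoint and mitotic genes each passed camera (adjusted p = 0.0343), at medians of -0.10, -0.14, -0.19 and -0.10. With the stricter filter Fanconi (adjusted p = 0.0390), checkpoint (0.0441), mitotic (0.0356) and NRF2 genes (0.0441) passed, and with an estimated correlation 0 of these lists did. The nucleotide excision repair list had a positive mean and the extracellular matrix list a negative mean, each against its median. Mitotic genes had a median of -0.09, replication-dependent histones 0.26, genes of nucleotide supply -0.12, NRF2 targets -0.12, the unfolded protein and ATF4 response -0.16, hypoxia and glycolysis genes -0.10 and cholesterol synthesis genes 0.06. The 16 neighbours of HMCES had a median of -0.08 (adjusted p = 0.216), with GATA2 at -0.94 ± 0.31 and ISY1 at -0.51 ± 0.21.

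Among cell identity genes, single members stood out while no marker list passed the threshold in the main test. Cancer-testis antigens had a median of -0.18 (adjusted p = 0.0516), and 3 members on the X chromosome passed when adjusted over the list alone. With the stricter filter the list passed camera (-0.20, adjusted p = 0.0215), and with the length trend removed it was at -0.09 (0.111). In the main data it had an adjusted p = 0.576 with an estimated correlation and 0.271 with fry. The 3 members were CTAG2 (log2 fold change -3.95 ± 0.49 SE, n = 2 and 2), which stood at 5.82 and 9.03 CPM in wild type and at 0.264 and 0.694 CPM in the clones, GAGE1 (-2.70 ± 0.59) and MAGEA3 (-0.80 ± 0.18), of which GAGE1 belongs to a family of near-identical copies. Epithelial markers had a median of 0.54 (adjusted p = 0.0516), with EPCAM at 1.41 ± 0.30 past the threshold over the list alone. The list passed with the length trend removed (0.51, adjusted p = 0.0343) and without clone 1 (0.25, adjusted p = 0.0111). Over all 4 libraries it had an adjusted p = 0.576 with an estimated correlation, with or without the length trend. Its median was 0.20 without clone 2 and 0.18 over the 9 members left by the stricter filter. Osteoblast markers were at -0.01 and extracellular matrix genes at 0.09, and in both lists COL1A1 (-1.89 ± 0.21) passed over the list alone. COL1A1 stood at 327 and 484 CPM in wild type and at 104 and 116 in the clones. Mesenchymal genes had a median of 0.05, with VIM at -0.78 ± 0.22, ZEB1 at -0.64 ± 0.16 and ACTA2 at 1.16 ± 0.27. Endothelial and haematopoietic markers, 7 and 8 of which were measured, had medians of 0.18 and 0.27, and clustered protocadherins had a median of 0.07.

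A set of genes was far lower in both clones. At least 4-fold lower in each clone than the wild type mean were 14 of the 13631 genes with at least 1 CPM in both wild type libraries. Of the 13650 genes with at least 1 CPM in both clones, 1 was at least 4-fold lower in each wild type library than the clone mean, LCAL1 (23 and 68 counts in wild type, 126 and 148 in the clones). Clone 1 had 34 such genes and clone 2 had 32. Independent lists of those sizes would share 0.0798 genes, but both lists use the same wild type mean. In simulations that redrew all 4 libraries without a change, the clones shared at most 4. With wild type 1 grouped with clone 1 or clone 2, 0 and 4 genes were that much lower in the other group, and 2 and 2 were higher. Besides NLRP2, CTAG2, GAGE1 and U2AF1 the 14 genes included the neuronal protein gene BASP1 (1201 and 2818 counts in wild type, 76 and 10 in the clones), the lysosomal protein gene GLMP (163 and 245 against 9 and 9), the homeobox gene DMBX1 (80 and 153 against 4 and 4), BCR (315 and 895 against 37 and 53) and LCN15 (99 and 134 against 1 and 3), all chosen after their values were seen. In the authors' TPM table LCN15 goes the other way, at 0 in both wild type libraries, and U2AF1 stands at 0.68 and 0.64 of wild type in clones 1 and 2 after rescaling. The signal recognition particle RNA genes RN7SL1 and RN7SL2 were also among them, but only wild type 2 set them apart. RN7SL1 stood at 265 counts in wild type 1 and 11863 in wild type 2, against 278 and 329 in the clones. Against wild type 1 alone, 12 of the 14 were still at least 4-fold lower in both clones. Of the 14, the authors' deposited table leaves out 11.

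The clones differed from wild type in a partly shared way. Over all tested genes, the covariance of their log2 changes was 0.0975, against a mean of 0.0566 in 100 simulations of unchanged clones that share the wild type libraries, a difference of 0.0409. With a different wild type library for each clone, so that no control was shared, the covariance was 0.0313 or 0.0370, against -0.000473 and -0.000359 simulated. The share of genes with the same sign was 71.4%, against 60.5% simulated. The simulations gave all libraries the same spread for a gene, whereas the wild type pair differed by a median of 0.27 log2 CPM and the clones by 0.16. A wide wild type pair raises the sign share and the covariance that use the shared wild type mean. Only the covariances without a shared control therefore bear on a shared change. The clones were at least 2-fold apart at 980 genes, and the wild type libraries at 884. Chromosome by chromosome, 0 of 23 passed, the lowest adjusted p being 0.401 for chromosome 22 (median log2 fold change -0.08). Without clone 2, chromosomes 16 and 22 passed, at 0.17 and -0.13 (adjusted p = 9.41e-05 and 0.0272 by camera at its preset correlation). Over all libraries both had an adjusted p = 1.00 with an estimated correlation and 0.948 with fry.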

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

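Settings added after the data were seen are the likelihood ratio tests, 1 CPM in every library, rescaled TPM, thinning, the removed length trend and separate wild type libraries per clone. With a library left out, the lone library of its group is assumed to vary like the other group, and for no difference below was the cause tested. The number of genes called (1 in the main test) was 13 with no filter, 49 with the DESeq2 Wald test, 44 with the exact test, 34 with limma on log2(TPM + 1), 21 on rescaled TPM, 22 with the likelihood ratio test and 1 CPM in every library, 53 with the likelihood ratio test alone and 0 in the main test with 1 CPM in every library. Of these, 13, 38, 38, 34, 21, 16, 47 and 0 changed at least 2-fold. Among the calls on TPM, as deposited or rescaled, 0 were called in the main test and 0 in the authors' deposited table. Leaving out 1 library gave 0 to 236 genes, of which 0 to 107 changed at least 2-fold, and a log2 fold change of HMCES from -1.55 to -0.68. The median log2 fold change of all genes was -0.42 on the TPM as deposited and 0.01 after rescaling, and on the former BTG2 (-0.042), MDM2 (-0.25), FAS (-0.027) and RBMS3 (-0.24) turned negative. Called lists (11 in the main test) numbered 0 with an estimated correlation, 0 with fry, 16 with the stricter filter, 16 with the length trend removed, 12 with wild type 2 thinned and 5 to 11 without 1 library. The covariance of the clones was 0.0742 with the stricter filter, 0.0313 with clone 1 against wild type 1 and clone 2 against wild type 2, and 0.0370 the other way round. At an adjusted p under 0.01 the authors' deposited table holds 14 genes.

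The direction of the extracellular matrix test turned with fry (median 0.092), DESeq2 size factors (0.097), library totals (0.11), wild type 2 thinned (0.085) and the length trend removed (0.076). Leaving out 1 library turned a direction for the gene RN7SL1 (-4.13 to 0.35) and for lists with these lowest and highest medians: extracellular matrix -0.023 to 0.12, protocadherins -0.11 to 0.19, nucleotide excision repair -0.088 to 0.042, histones -0.45 to 0.65, unfolded protein response -0.37 to 0.013, cholesterol synthesis -0.051 to 0.16, osteoblast markers -0.14 to 0.069, end joining -0.11 to 0.028, endothelial markers 0.098 to 0.38 and HOX genes 0.058 to 0.33. For chromosome 16 the range was -0.060 to 0.17. Of all other values of lists under an alternative, 316 stayed the same, 43 lost their call and 18 gained one, and for named genes these counts were 827, 3 and 130.

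With the replicate number as a replicate block, 9 genes were called (2 up, 7 down), all 9 changed at least 2-fold, 12 lists were called (6 up, 6 down), with cancer-testis antigens (adjusted p = 0.0472) and the unfolded protein response (0.0298) gained and HOX genes lost (0.0652), the epithelial median was 0.37, and the extracellular matrix test turned (median 0.076). The deviations of wild type 1 and clone 1 from their group means correlated at r = -0.0206 across genes, so no effect of the replicate number was seen. With so few libraries that value cannot exclude pairing, and the labels do not state any.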

Other observations

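The clones differed from each other along chromosomes 16, 22 and 2. Over the 690 tested genes of chromosome 16, clone 2 was below clone 1 by a median of -0.32 log2 CPM, whereas 10000 random sets of that size ran from -0.04 to 0.04. Chromosome 22, with 389 genes, was higher in clone 2 by 0.17 (random sets -0.05 to 0.05), but it also differed by 0.16 between the wild type libraries (-0.08 to 0.10). Chromosome 16 differed by 0.02 between the wild type libraries. Chromosome 2, with 1091 genes, was higher in clone 2 by 0.06 (random sets -0.02 to 0.03) and differed by 0.03 between the wild type libraries (-0.04 to 0.07). For comparison, chromosome 19 differed by 0.064 between the wild type libraries (random sets -0.034 to 0.064), so a shift of about that size also lay between libraries without the knockout. Replication-dependent histone genes, which are made in S phase, did not pass over all libraries (adjusted p = 0.478 by camera, and adjusted p = 0.902 with an estimated correlation). Their median log2 fold change was 0.65 for clone 1 alone and -0.45 for clone 2 alone, a difference that was not tested, and the wild type libraries differed by 0.57. All 4 observations were picked after the values were seen.

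Of the tests below, those on genes at least 4-fold lower were chosen after the result was seen, and the length tests after the length trend was seen.

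Targets of p53 were higher in both clones. If wild type 2 were the source, leaving it out would end the shift, but the median was then 0.48 (adjusted p = 1.10e-14 by camera at its preset correlation), which argues against it, although over all 4 libraries the list did not pass (adjusted p = 0.576 with an estimated correlation, 0.271 with fry). Gene length bias in that library is argued against too, since with the trend removed the median was 0.36 (adjusted p = 9.61e-10, and adjusted p = 0.576 with an estimated correlation). Cloning or long passage rather than loss of HMCES cannot be told apart, because there are 0 control clones. The hypothesis that loss of HMCES raises p53 activity could be tested by putting HMCES back into each clone and measuring CDKN1A, ZMAT3 and RRM2B.

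Of the 14 genes at least 4-fold lower in both clones, 12 were also that low against wild type 1 alone, which argues against wild type 2 as the source of the set, RN7SL1 and RN7SL2 apart. Reads shared with gene copies or lost by the mapping quality filter remain open, as 9 of the 12 genes that the TPM table measures were at least 2-fold lower there in both clones (exact 95% interval 42.8% to 94.5%), with LCN15 the other way, and the rule was made stricter after that count was seen. That interval treats the genes as independent draws, but they were picked from these same libraries. The 9 include RN7SL1 and RN7SL2, which only wild type 2 set apart in the counts. Simulated libraries with no change and the fitted spread between libraries gave at most 4 such genes in 100 simulations. A common ancestor of the clones that had already silenced these genes may also be the source, and with 0 control clones that cannot be told apart from loss of HMCES. Sequencing the parent culture cell by cell for NLRP2 and BASP1 would test it.

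Ribosomal protein genes were lower in both clones. Wild type 2 standing apart fits as the source of most of this, since without that library the median went from -0.30 to -0.093. The list still passed camera then at its preset correlation (adjusted p = 0.00129), but over all 4 libraries it did not pass (adjusted p = 0.605 with an estimated correlation, 0.439 with fry), so whether a smaller difference is left stays open. Gene length bias of that library cannot be told apart from other differences in it, as the median with the trend removed was -0.17 (adjusted p = 7.77e-05, and adjusted p = 0.576 with an estimated correlation), between the bounds set for either answer. Loss of HMCES stays open for any part that is left.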
